A study of Homo sapiens with 42 samples.

How the data were processed

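RNA-seq was analysed from 42 libraries of H1 human embryonic stem cells, in 21 groups of 2, as 3 differentiation systems of 7 groups each. Groups were taken from the sample titles, and the treatment label gave the compound at 10 µM or 0.1% DMSO. The labels give 2 µg of total RNA per library, and do not name the library kit or its strandedness. The design text gives 8 days of NNE differentiation while the growth protocol runs to day 10, so the NNE groups are given here without a day.

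Per the submitters' processing notes, HISAT2, Bowtie2, RSEM and DESeq2 were used with the GRCh38.p13 build; the role and version of each are not given in the sources used here. The deposited table held, per the file headers, a read count per gene and library, and its fractional values were read as the expected counts that the authors estimated, as RSEM gives. The deposited TPM values are transcript abundances that the authors scaled to gene length and library size, and they summed to between 993074 and 996404 per library over the 18796 genes used here. The deposited FPKM values and the authors' group averages were not used for any test. The authors also deposited a log2 fold change and a p-value and q-value from DESeq2 for each compound against DMSO, per the file headers. The table had 93 blank lines, which were not analysed here. Gene symbols, gene IDs and coordinates are those of the table.

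Expected counts were rounded to whole numbers, which moved a library total by at most 0.0004%. Totals were 18918928 to 19842938 per library, so depth differed little between groups. Tests used edgeR 4.0.16 in R 4.3.3: the quasi-likelihood F test on TMM-normalised counts, after the default filter on low counts by group, with Benjamini-Hochberg adjustment within each contrast and an adjusted p under 0.05 as the threshold. Each system was fitted on its 14 libraries, so that its 7 groups shared 1 estimate of the spread; 15278, 15670 and 14966 genes were tested at day 8, day 16 and in NNE. The 18 comparisons with DMSO, the mean of the 6 compounds, any difference among them and 27 structural pairs came from these fits. That mean gives each compound equal weight, so 1 compound with large changes can carry it. The difference of each effect between days was tested on the 28 E6 libraries, and the DMSO groups were compared in a fit of all 42. A standard error is the log2 change divided by the square root of its F value. TPM means and SDs are over the 2 libraries of a group and describe the level. The text gives log2 changes from the counts.

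The lists of genes, the rule for named genes, the tests and the alternatives named below were fixed before the data were examined, except where stated. Of 30 lists of lineage, signalling, metabolic and stress genes, 27 had at least 5 tested members in some system, and the others were not analysed here. Lists were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, adjusted over lists and compounds within a system, and again with the correlation estimated from the data. Named genes were, per compound and system, the 2 with the largest rise and the 2 with the largest fall among genes past the threshold (bare locus identifiers left out) with a mean log2 CPM of at least 1 and both treated libraries beyond both DMSO libraries. To these were added up to 4 members of each list with the smallest p per system, or the first 2 where none passed, 3 members of each lineage list for the DMSO groups, the 2 genes with the smallest p of each structural pair and each difference between days, and the 5 genes called most often in 1 direction. XAGE2, KRT6A and the histone genes have near-identical copies, between which reads can be split, so their values are uncertain. Several other genes of such families that the rule gave are not described. The text describes a selection of the genes that this rule gives, and some of the others are not reported here.

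Alternatives were DESeq2 1.42.0 on the same libraries, RLE normalisation, no filter on low counts, the replicate number as an additive term, a fit of only the libraries compared, and leaving out each library in turn. A group left with 1 library is then assumed to vary like the other groups. DESeq2 adjusted each comparison over the genes that its own filter kept, such as 1647 for PFHxA minus PFBA at day 8. Its counts are therefore not adjusted over the same genes as those of edgeR. Counts of list members without 1 library, camera on the 50 hallmark sets of the deposited table and on differences between days, and intervals for list means, also over PPAR targets called and not called with PFOA, were added after seeing the data. List means are averages of log2 CPM with a prior count of 2. Their 95% intervals use the spread within the 7 groups and are not adjusted for the number of lists and pairs.

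The fits were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed. For PFOA against DMSO, edgeR recovered 71.6%, 89.6% and 100% of genes changed 1.5-fold, 2-fold and 4-fold at day 8 (15082 genes), 74.6%, 82.1% and 98.5% at day 16 (15430 genes), and 49.3%, 79.1% and 95.5% in NNE (14709 genes), with 8 to 11 calls among unchanged genes. Shared controls were simulated with 20 draws of unchanged groups for correlations and 5 for shared calls. Count tables of replicates differed by more than sampling noise in every group (chi-square per degree of freedom of 2.74 to 13.43), so each library counts once. Log2 fold changes of the authors' deposited table correlated at 0.999 to 1 across genes with those computed here.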

Results

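Gene expression was measured by RNA-seq in H1 cells, an established human embryonic stem cell line, that differentiated in 3 systems in the presence of a per- or polyfluoroalkyl substance (PFAS) or of its solvent. In the first 2 systems the cells grew as a monolayer in Essential 6 (E6) medium, which lacks the factors that hold stem cells undifferentiated, and were collected on day 8 or day 16. In the third, BMP4 with inhibitors of other growth factor signals directed the cells to non-neural ectoderm (NNE), the layer from which epidermis forms. PFOA, PFHxA and PFBA are perfluorinated carboxylic acids of decreasing chain length, and PFOS, PFHxS and PFBS are sulfonic acids of decreasing chain length. Each was present at 10 µM from the start of differentiation, and control cells received 0.1% DMSO. The 7 groups of each system had 2 libraries each, which gave 42 libraries in 21 groups. Each library held between 18918928 and 19842938 expected counts and between 16651 and 17229 genes above 0. The 10 most abundant genes took 4.07% to 6.98% of a library. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

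The DMSO groups show the cell states in which the compounds were tested. LIN28A, an RNA-binding protein of stem cells, fell from day 8 to day 16 by 3.03 ± 0.16 on the log2 scale (SE, n = 2 per group; adjusted p = 3.11e-15), from 1540 to 217 TPM, a transcript abundance scaled to gene length and library size, and the DNA methyltransferase DNMT3B fell from 162 to 27.4 TPM. TP63, a transcription factor of stratified epithelium (gene ID 8626, GRCh38.p13 chromosome 3, 189596746 to 189952744), rose by 4.88 ± 0.152 (adjusted p = 5.77e-20) from 3.3 to 127 TPM. The ligand WNT6 rose from 3.64 to 177 TPM, keratin KRT17 from 0.38 to 84.1 TPM and the forebrain factor EMX2 from 0.41 to 54.9 TPM, while the neural crest receptor NGFR fell from 64.3 to 5.44 TPM. KRT5, KRT14, XAGE2 and FOXE3 were listed at 0 in both day 8 DMSO libraries and at 10.2, 1.76, 50.2 and 9.34 TPM at day 16.

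NNE cells were compared with day 8 E6 cells. SOX2, a factor of neural and pluripotent cells (gene ID 6657, chromosome 3, 181704514 to 181727934), stood at 0.185 TPM in NNE against 438 TPM at day 8, a log2 change of -11.12 ± 0.31 (SE, n = 2 per group; adjusted p = 5.47e-22), and the forebrain factor SIX3 at 0.025 against 427 TPM. Of transcripts that amnion and surface ectoderm carry, VTCN1 reached 1120 against 0.74 TPM, GABRP 1690 against 1.56 TPM and KRT17 53.2 against 0.38 TPM. The mesenchymal factor SNAI2 rose from 1.31 to 217 TPM, the actin gene ACTC1 from 68.4 to 3250 TPM and the mesodermal factor OSR1 from 0.025 to 32.2 TPM. DLX5, a factor of the neural plate border and a member of the fixed non-neural ectoderm list, fell from 328 to 0.14 TPM. edgeR's quasi-likelihood test called 9812 genes between day 16 and day 8 (4935 higher, 4877 lower) and 12136 between NNE and day 8 (6016 higher, 6120 lower).

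Which genes PFOA altered at day 8 bears on early global developmental toxicity, the purpose the study states for the E6 system. Genes of glycolysis and the hypoxia response rose together: 16 of the 18 list members passed, and 17 when adjusted over the list alone, with a median log2 change of 0.85. NDRG1, a hypoxia-responsive gene (gene ID 10397, chromosome 8, 133237171 to 133297304), rose by 1.32 ± 0.098 (SE, n = 2 per group; adjusted p = 6.11e-06), from 8.73 ± 0.0283 to 21.1 ± 0.46 TPM (SD). PFKFB4, which sets the level of a glycolytic activator (gene ID 5210, chromosome 3, 48517684 to 48562383), rose by 1.11 ± 0.089 (adjusted p = 7.54e-06), and the collagen hydroxylase P4HA1 went from 204 to 355 TPM. Enzymes of cholesterol synthesis rose by less: 12 of 23 passed (15 adjusted over the list alone), and the median was 0.22. INSIG1, a sterol-responsive regulator, rose by 0.70 ± 0.081 and the squalene epoxidase SQLE by 0.38 ± 0.053. Non-neural ectoderm genes fell, 13 of 18 over all genes and over the list alone, with a median of -0.71. DLX5 fell from 328 to 150 TPM, DLX3 from 37.6 to 15.8, the epithelial factor GRHL3 from 114 to 51.1 and the cadherin CDH1 from 474 to 343.

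Other gene groups moved with PFOA at day 8 as well. Of 10 detected neural crest genes 5 fell (6 adjusted over the list alone), among them PAX7, which went from 13 to 4.8 TPM, and of 10 amnion and trophoblast genes 4 fell (5 adjusted over the list alone), with ELF5 at 3.22 against 9.22 TPM. The chemokine CXCL14 fell by 2.38 ± 0.419 on the log2 scale (SE, n = 2 per group; adjusted p = 0.00193), from 17 ± 6.78 to 3.16 ± 1.31 TPM (SD). Of 15 p53 targets 8 fell and 1 rose (9 and 1 adjusted over the list alone), with ZMAT3 lower by a log2 change of -0.52 and TIGAR by -0.43. The proneural factor NEUROG2 rose from 6.14 to 12.7 TPM and LHX2, a forebrain factor, from 77.7 to 119 TPM. Of 19 cell cycle genes 11 rose and 1 fell, also over the list alone. GAD2, an enzyme that makes the transmitter GABA, rose from 1.38 to 3.8 TPM and NDUFA4L2, a hypoxia-responsive mitochondrial protein, from 4.09 to 11.6 TPM.

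edgeR called 2032 genes for PFOA at day 8, 1039 higher and 993 lower, of which 182 changed at least 2-fold. By camera, 12 lists passed: glycolysis and hypoxia (adjusted p = 2.11e-40) and non-neural ectoderm (adjusted p = 2.68e-12) were lost with a correlation estimated from the data (adjusted p = 0.0859 and adjusted p = 0.352 with an estimated correlation). Cholesterol synthesis (adjusted p = 1.47e-09) was the only list call of any compound and system that held (adjusted p = 0.0283 with an estimated correlation). The lists of p53 targets, cell cycle, neural crest and amnion genes had adjusted p = 4.3e-05, adjusted p = 0.000144, adjusted p = 5.56e-05 and adjusted p = 0.00091, against adjusted p = 0.397, adjusted p = 0.53, adjusted p = 0.385 and adjusted p = 0.444 with an estimated correlation. The call count was 535 without DMSO replicate 1, 1263 without PFOA replicate 1 and 499 without PFOA replicate 2. Glycolysis had 14 called members in each of these 3 fits. Non-neural ectoderm went to 7 members without DMSO replicate 1 and 6 without PFOA replicate 2. Cholesterol synthesis went to 6 without DMSO replicate 1, and cell cycle to 0 without DMSO replicate 1 and 1 without PFOA replicate 2. The p53 targets went to 4 without PFOA replicate 2, neural crest genes to 3 without DMSO replicate 1 and 1 without PFOA replicate 2. Amnion genes went to 1 without DMSO replicate 1, PFOA replicate 1 or PFOA replicate 2. The non-neural ectoderm median was -0.47 without PFOA replicate 2.

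With PFOS at day 8, CYP26C1, which degrades retinoic acid (gene ID 340665, chromosome 10, 93060798 to 93069540), rose by 2.81 ± 0.41 on the log2 scale (SE, n = 2 per group; adjusted p = 0.000698), from 6.54 ± 4.25 to 45.6 ± 19.2 TPM (SD). BMP pathway targets rose in 6 of 11 cases over all genes and over the list alone, with BAMBI at 42.8 against 11.5 TPM and BMP4 at 83.2 against 47.5 TPM. Cardiac and muscle genes ACTC1 and NKX2-5 rose by 1.01 and 2.5. The collagen gene COL1A1 rose by 0.88 ± 0.074 and COL5A2 fell by 0.94 ± 0.105. Matrix genes went both ways (3 higher and 2 lower of 16; 6 and 3 adjusted over the list alone), with a median of 0.14 (0.23 without DMSO replicate 1) and a mean of -0.13. Among glycolysis and hypoxia genes 9 of 18 rose (13 adjusted over the list alone), with ADM, a hypoxia-responsive peptide, at 74.7 against 31.5 TPM. The eye and forebrain factor PAX6 fell from 110 to 74.4 TPM and the immediate early gene FOSB from 3.55 to 1.12 TPM, and 6 of 15 p53 targets fell (9 adjusted over the list alone).

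For PFOS at day 8 edgeR called 905 genes, 573 higher and 332 lower. The camera calls of glycolysis (adjusted p = 1.8e-20), p53 targets (adjusted p = 2.75e-09), BMP targets (adjusted p = 2.24e-08), cardiac and muscle (adjusted p = 0.00102), retinoid and HOX (adjusted p = 0.00133), cranial placode (adjusted p = 0.00255) and matrix genes (adjusted p = 0.0146) had adjusted p = 0.264, adjusted p = 0.308, adjusted p = 0.352, adjusted p = 0.308, adjusted p = 0.419, adjusted p = 0.444 and adjusted p = 0.444 with an estimated correlation. The placode list had 3 higher and 1 lower of 8 (6 and 1 adjusted over the list alone), and the retinoid list 4 higher of 8 (5 adjusted over the list alone). The gene count was 422 without DMSO replicate 1, 548 without DMSO replicate 2 and 325 without PFOS replicate 1. The retinoid genes went to 2, 1 and 1 in the same fits, the placode genes to 1 higher without DMSO replicate 2 or PFOS replicate 1, and the p53 targets to 3 without PFOS replicate 1.

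At day 8 PFBA, PFHxA and PFHxS moved glycolysis genes in the direction seen with PFOA. Of the 18 members 7 rose with PFBA, 7 with PFHxA and 7 with PFHxS (10, 10 and 12 adjusted over the list alone), with medians of 0.33, 0.40 and 0.38. The camera calls had adjusted p = 3.22e-13, adjusted p = 1.65e-13 and adjusted p = 2.17e-15, and adjusted p = 0.308 with an estimated correlation for each of the 3. With PFBS the list had a median of 0.19 (0.31 without DMSO replicate 2 or PFBS replicate 1) and adjusted p = 1.35e-09 by camera, and adjusted p = 0.352 with an estimated correlation. For PFBS 6 members were higher adjusted over the list alone, and over all genes 4 rose without DMSO replicate 2 and 0 in edgeR with all libraries. Non-neural ectoderm genes fell in 8, 5 and 3 of 18 cases (9, 14 and 10 adjusted over the list alone; adjusted p = 2.24e-08, adjusted p = 1.05e-14 and adjusted p = 8.2e-08, and adjusted p = 0.42, adjusted p = 0.352 and adjusted p = 0.425 with an estimated correlation). CXCL14 fell with all 3, from 17 TPM to 4.16, 4.8 and 4.86 TPM. These 3 calls were lost without DMSO replicate 1 (adjusted p = 0.17, adjusted p = 0.365 and adjusted p = 0.284). They were also lost without PFBA replicate 2 (adjusted p = 0.153), PFHxA replicate 1 (adjusted p = 0.0805) and 2 (adjusted p = 0.19) and PFHxS replicate 2 (adjusted p = 0.313).

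edgeR called 853 genes for PFBA (409 higher, 444 lower), 372 for PFHxA (142 higher, 230 lower) and 384 for PFHxS (194 higher, 190 lower). PFBS gave 0 calls in edgeR, with 1951 genes at an unadjusted p under 0.05, and 63 calls in DESeq2, which adjusted over 7651 genes. Without DMSO replicate 1 the counts of PFBA, PFHxA and PFHxS were 13, 0 and 4, and glycolysis members rose in 1, 0 and 0 cases. Without DMSO replicate 2 PFHxA had 684 calls and PFBS 114, and PFBS had 1 without its replicate 2. PFBA had 324 calls without its replicate 1 and 5 without its replicate 2, PFHxA 0 and 74, and PFHxS 0 without its replicate 2. The mean of the 6 compounds against DMSO gave 1397 genes (650 higher, 747 lower), but 16 without DMSO replicate 1.

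**Figure D1:**
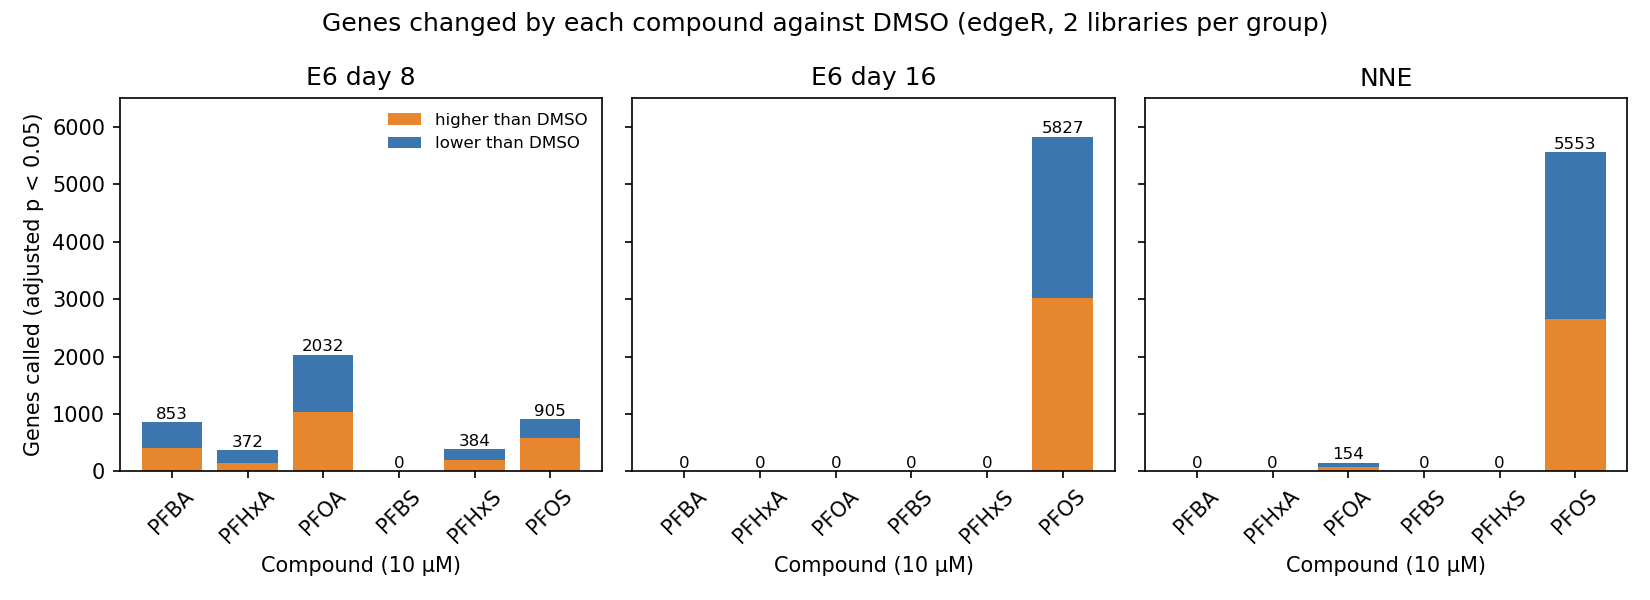
Number of genes that edgeR called against DMSO (adjusted p under 0.05; vertical axis, a linear scale from 0) for each compound in each system, with higher genes in orange and lower genes in blue, from 2 libraries per group. PFOS stands at 5827 genes at day 16 and 5553 in NNE, and the other compounds at 0 at day 16.

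At day 16 PFOS lowered neural ectoderm genes. All 16 members of the neuroectoderm list fell, over all genes and over the list alone, with a median log2 change of -2.22. OTX2 went from 199 to 85.9 TPM, LHX2 from 66.1 to 12.8 TPM, and DLK1 from 112 to 8.46 TPM. The pluripotency and neural factor SOX2 fell from 142 to 41.4 TPM, LIN28A from 217 to 81.3 TPM, and the mesendodermal factor EOMES (gene ID 8320, chromosome 3, 27715953 to 27722713) from 3.74 to 0.075 TPM. Extracellular matrix genes rose, 16 of 18 over all genes and over the list alone. The proteoglycan DCN (gene ID 1634, chromosome 12, 91140484 to 91182817) rose by 7.21 ± 0.284 (SE, n = 2 per group; adjusted p = 1.06e-09), from 0.445 ± 0.177 to 53.8 ± 6.58 TPM (SD). LUM rose from 7.81 to 211 TPM, COL1A1 from 182 to 1020 TPM and FN1 from 1200 to 2880 TPM. TGFBI, a matrix protein (gene ID 7045, chromosome 5, 136028988 to 136067111), rose from 56.5 to 1690 TPM.

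Amnion and trophoblast, retinoid and HOX genes also moved with PFOS at day 16. Of 12 amnion and trophoblast genes 8 rose and 1 fell, also over the list alone. GABRP, a GABA receptor subunit (gene ID 2568, chromosome 5, 170782841 to 170814898), rose by 4.35 ± 0.256 (adjusted p = 1.98e-08; SE, n = 2 per group), from 154 ± 31.8 to 2830 ± 409 TPM (SD). HAND1 rose from 14.2 to 224 TPM. Of 11 retinoid and HOX genes 8 rose and 1 fell, also over the list alone, with HOXB2 at 35.9 against 0.595 TPM and CYP26B1 at 19.7 against 1.13 TPM. HOXB3 stood at 6.41 TPM and was listed at 0 in both DMSO libraries. Cardiac troponin TNNT2 rose from 12.6 to 117 TPM. NEUROD1, a factor of sensory neurons, rose from 0.78 to 18.5 TPM, whereas the neuronal microtubule gene MAP2 fell from 60.3 to 22 TPM. Of 17 neuronal genes 8 rose and 3 fell (10 and 4 adjusted over the list alone), without a camera call (adjusted p = 0.424). Basal keratin KRT5 fell from 10.2 to 1.56 TPM.

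With PFOS at day 16, 14 of 15 p53 targets fell, over all genes and over the list alone, with a median of -0.70. The death receptor TNFRSF10B went from 198 to 70.4 TPM and SPATA18 from 20.3 to 5 TPM. Of 18 genes of the unfolded protein and integrated stress responses 13 fell and 1 rose (13 and 3 adjusted over the list alone), among them PSAT1 (488 to 114 TPM) and ASNS (356 to 90.4 TPM), enzymes of serine and asparagine synthesis. Glycolysis and hypoxia genes mostly fell, 12 of 17 against 3 higher (13 and 3 adjusted over the list alone), with LDHA at 541 against 1120 TPM but NDRG1 at 111 against 44.7 TPM. Of 19 cell cycle genes 12 fell (14 adjusted over the list alone).

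edgeR called 5827 genes for PFOS at day 16, 3018 higher and 2809 lower, of which 1324 changed at least 2-fold, and 3777 without PFOS replicate 2. The camera calls of matrix (adjusted p = 1.29e-21), p53 targets (adjusted p = 5.77e-15), neuroectoderm (adjusted p = 2.42e-13), amnion (adjusted p = 8.09e-10) and retinoid genes (adjusted p = 3.23e-06) had adjusted p = 0.152, adjusted p = 0.191, adjusted p = 0.227, adjusted p = 0.157 and adjusted p = 0.152 with an estimated correlation. Those of the stress response (adjusted p = 4.25e-05), glycolysis (adjusted p = 0.000914), cell cycle (adjusted p = 0.00315) and pluripotency genes (adjusted p = 0.00598; 1 higher and 6 lower of 13, also over the list alone) had adjusted p = 0.629, adjusted p = 0.469, adjusted p = 0.629 and adjusted p = 0.562 with an estimated correlation. Cell cycle members went from 12 to 6 without PFOS replicate 2.

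The other 5 compounds gave 0 calls each at day 16 in edgeR. The genes at an unadjusted p under 0.05 numbered 268 for PFBA, 715 for PFHxA, 998 for PFOA, 431 for PFBS and 357 for PFHxS, and DESeq2 called 3, 2, 16, 0 and 4. PFHxA had 12 calls without DMSO replicate 1 and 1 without its replicate 1, and PFOA 3 without DMSO replicate 2 and 1 without its replicate 1. Some lists passed camera although no member passed over all genes. With PFOA the BMP targets had a median of 0.23 (adjusted p = 7.6e-10; adjusted p = 0.152 with an estimated correlation), and 4 of 11 were higher adjusted over the list alone. Glycolysis genes with PFOA had a median of 0.15 (adjusted p = 1.84e-09; adjusted p = 0.206 with an estimated correlation), which was 0.24 without DMSO replicate 1 and 0.10 without PFOA replicate 2. With PFBS the WNT targets had a median of 0.093 (adjusted p = 0.00525; adjusted p = 0.261 with an estimated correlation). It was 0.16 and 0.18 without DMSO replicate 1 and 2, and 0.02 and 0.16 without PFBS replicate 1 and 2. For the last 2 lists 0 members passed over the list alone in edgeR. The mean of the 6 compounds gave 3 genes, named here after their values were seen. INPP5D and PRRG3 were lower (log2 changes of -0.63 and -1.55) and ADAMTS1 was higher (0.48). This mean includes PFOS, the only compound with calls in edgeR at day 16, so these 3 genes show no shared response by themselves. Without DMSO replicate 1 this count was 0. It was 35 without DMSO replicate 2, 24 without PFOS replicate 1, 13 without PFBS replicate 2 and 9 without PFBA replicate 2, and 1 without PFHxS replicate 1, PFHxS replicate 2 or PFOS replicate 2. INPP5D lost its call without DMSO replicate 1 alone (adjusted p = 0.123), and PRRG3 also without PFHxA replicate 2, either PFHxS library or PFOS replicate 2 (adjusted p of at most 0.139). ADAMTS1 lost its call without every library except DMSO replicate 2, PFBA replicate 2, PFBS replicate 2 and PFOS replicate 1 (at most 0.313).

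**Figure D2:**
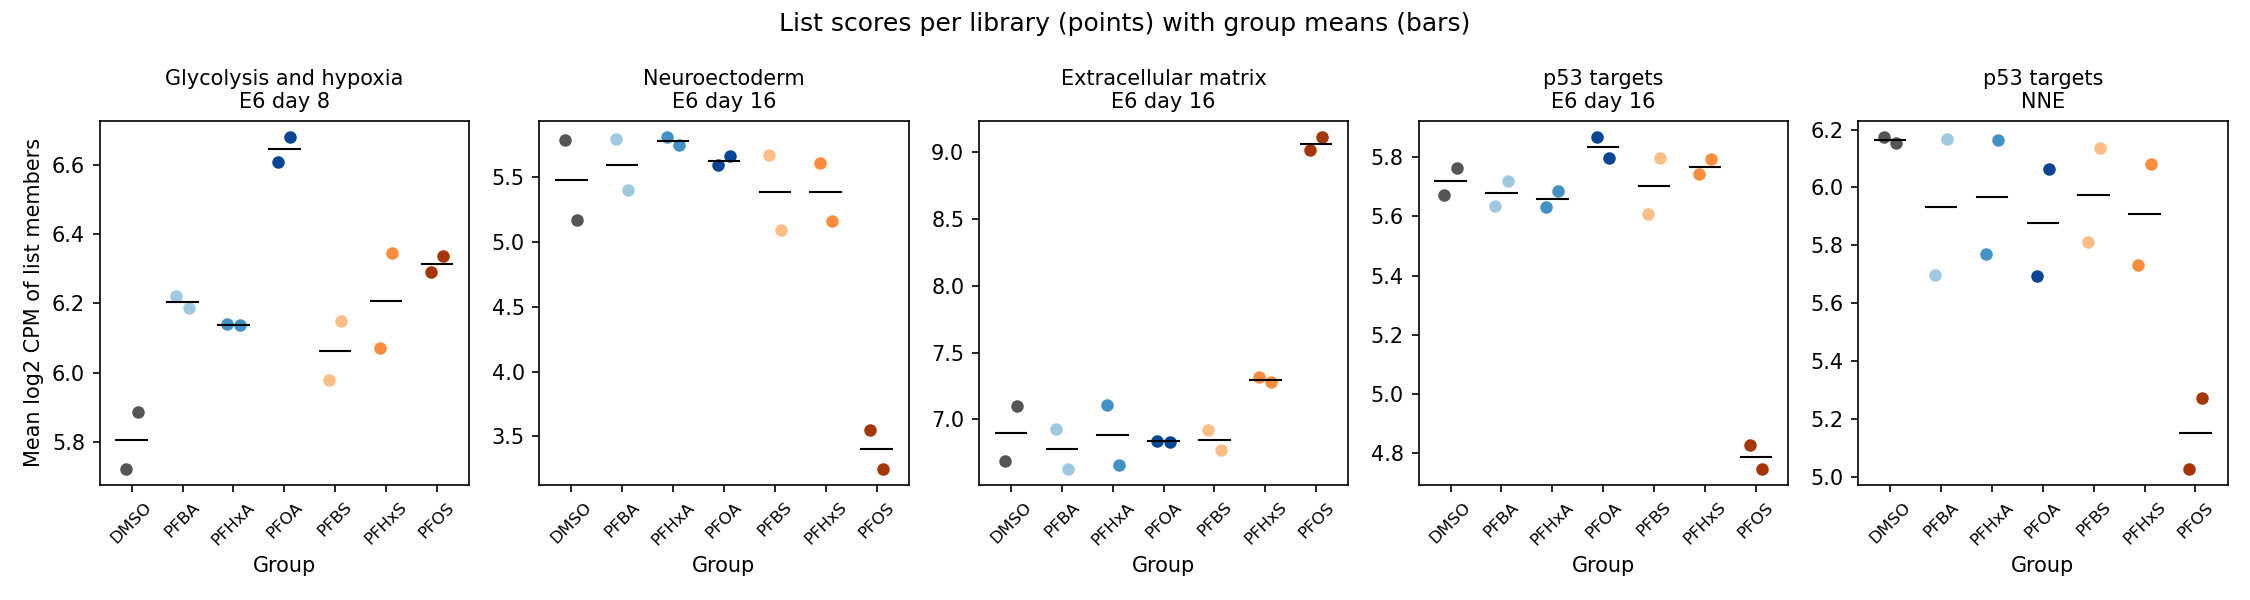
Mean log2 expression of list members per library (vertical axes, log2 CPM averaged over members), by group (horizontal axes), with 1 point per library and a bar at the mean of the 2. Glycolysis genes at day 8 are highest in the 2 PFOA libraries, neuroectoderm genes at day 16 and p53 targets at day 16 and in NNE are lowest in the 2 PFOS libraries, and matrix genes at day 16 are highest in the 2 PFOS libraries.

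In NNE cells, the study's model of early skin development, PFOS was compared with DMSO. The receptor CD44 (gene ID 960, chromosome 11, 35139168 to 35232402) fell by 5.32 ± 0.51 on the log2 scale (SE, n = 2 per group; adjusted p = 3.63e-05), from 58.4 ± 30.0 to 1.42 ± 0.566 TPM (SD), and the phosphatase PTPRR from 6.76 to 0.05 TPM. Of 12 keratinocyte genes 4 fell and 1 rose, also over the list alone. The laminin chain LAMB3 went from 40 to 3.9 TPM, SFN from 243 to 65.2 TPM and KRT17 from 53.2 to 12.3 TPM. KRT6A, at 0.71 TPM in DMSO, was listed at 0 in both PFOS libraries. NPY, a neuropeptide (gene ID 4852, chromosome 7, 24284190 to 24291862), rose by 5.35 ± 0.247 (adjusted p = 1.22e-06), from 31.9 ± 16.4 to 1310 ± 214 TPM (SD). Non-neural ectoderm genes went both ways, 4 higher and 8 lower of 16 (5 and 8 adjusted over the list alone; adjusted p = 0.37, no call). WNT6 rose from 26.7 to 81.2 TPM, while GATA2 fell from 80.9 to 46.5 and TFAP2A from 255 to 165 TPM.

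The p53 targets fell with PFOS in NNE too, 12 of 15 over all genes and over the list alone, with a median of -1.05. The stress cytokine GDF15 went from 107 to 12.9 TPM and the nuclease AEN from 68.4 to 33 TPM. The mean log2 expression of the list was 5.03 and 5.27 in the 2 PFOS libraries of NNE and between 5.69 and 6.17 in the others. Replicate 1 of the other 5 compounds (5.69 to 5.81) lay below their replicate 2 (6.06 to 6.17). Of 18 stress response genes 15 fell, also over the list alone, with ASNS at 55.9 against 170 TPM. Neuronal genes STMN2 and TUBB3 fell from 24.9 to 0.785 and from 138 to 22.3 TPM (3 of 8 in the list fell, also over the list alone). Of 11 retinoid and HOX genes 5 rose and 1 fell, also over the list alone, with HOXB4 at 13.2 against 2.86 TPM. Matrix genes went both ways, 4 higher and 6 lower of 18 (5 and 6 adjusted over the list alone), and the test pointed down (adjusted p = 0.751, no call) while the median was 0.16. That median was 0.001 without DMSO replicate 1, 0.26 without DMSO replicate 2, and 0.06 and -0.02 without PFOS replicate 1 and 2. DCN and LUM rose from 2.34 to 34 and from 987 to 2550 TPM, and COL4A2 fell from 269 to 98.2 TPM. ACTC1 fell from 3250 to 602 TPM and the WNT target AXIN2 rose from 1.66 to 7.48 TPM. The desaturases SCD and FADS2 fell from 941 to 486 and from 259 to 127 TPM.

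edgeR called 5553 genes for PFOS in NNE, 2645 higher and 2908 lower, of which 1365 changed at least 2-fold, and 3599 without DMSO replicate 1 and 3465 without PFOS replicate 1. Camera called p53 targets (adjusted p = 4.33e-06), the stress response (adjusted p = 5.87e-05), keratinocyte (adjusted p = 0.000298), retinoid (adjusted p = 0.00681) and neuronal genes (adjusted p = 0.0253), with adjusted p = 0.396, adjusted p = 0.307, adjusted p = 0.248, adjusted p = 0.351 and adjusted p = 0.294 with an estimated correlation. Immediate early and heat shock genes (8 lower and 1 higher of 14, also over the list alone) had adjusted p = 0.0241, and adjusted p = 0.351 with an estimated correlation.

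With PFOA in NNE, PDK4, which restrains pyruvate oxidation (gene ID 5166, chromosome 7, 95583499 to 95596516), rose by 2.98 ± 0.285 on the log2 scale (SE, n = 2 per group; adjusted p = 0.00823), from 1.52 ± 0.813 to 12 ± 0.976 TPM (SD), and ANGPTL4, which inhibits lipoprotein lipase, rose from 2.64 to 15.6 TPM. Of 17 PPAR target genes 4 rose, also over the list alone. With PFOS 4 rose and 3 fell, also over the list alone, without a camera call (adjusted p = 0.326). PFOS raised PDK4 by 1.55 ± 0.292, ANGPTL4 by 1.71 ± 0.346 and CPT1A, which brings fatty acids into mitochondria, by 1.32 ± 0.155, named after their values were seen. The log2 change of PDK4 with PFHxS was 1.30 ± 0.294 (adjusted p = 0.13), and camera called the list for PFHxS (adjusted p = 0.0435; adjusted p = 0.354 with an estimated correlation). The cytokine IL32 fell from 125 to 25 TPM and DDIT4, a stress-induced inhibitor of growth signalling, from 276 to 102 TPM. Of 18 stress response genes 2 fell (12 adjusted over the list alone). The PPAR list had adjusted p = 3.02e-05 and the stress response adjusted p = 2.44e-09 by camera, and both had adjusted p = 0.248 with an estimated correlation. Replication-dependent histone genes had a median of 0.56, and of 0.31 without PFOA replicate 1 (adjusted p = 0.00327; adjusted p = 0.351 with an estimated correlation; 3 of 7 higher adjusted over the list alone).

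edgeR called 154 genes for PFOA in NNE, 71 higher and 83 lower, and DESeq2 called 654. The edgeR count was 1 without DMSO replicate 1, 696 without DMSO replicate 2, 0 without PFOA replicate 1 and 1 without PFOA replicate 2, and the PPAR count was 1, 4, 0 and 1. PDK4 lost its call without PFOA replicate 1 (adjusted p = 0.1). ANGPTL4, IL32 and DDIT4 lost theirs without DMSO replicate 1, PFOA replicate 1 or PFOA replicate 2 (adjusted p from 0.125 to 0.303). PFBA, PFHxA, PFBS and PFHxS gave 0 calls each in edgeR. The genes at an unadjusted p under 0.05 numbered 1060, 1470, 1938 and 2176, and DESeq2 called 0, 5, 48 and 275. Without DMSO replicate 2 the counts were 104, 242, 114 and 518. Stress response and NRF2 target genes had negative medians with these 4, between -0.43 and -0.33 and between -0.30 and -0.18. Camera called both lists for all 4, with an adjusted p of at most 4.33e-06 and 0.00305, and at least 0.248 and 0.307 with an estimated correlation. Without DMSO replicate 1 the stress response medians of PFBA, PFHxA, PFBS and PFHxS were -0.091, -0.19, -0.12 and -0.28, and the NRF2 medians of PFBA and PFHxA -0.11 and -0.15. The stress response median of PFHxA was -0.51 without DMSO replicate 2, and the NRF2 median of PFBA -0.16 and -0.42 without PFBA replicate 1 and 2. The mean of the 6 compounds gave 1404 genes (544 higher, 860 lower), and 0 without DMSO replicate 1.

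**Figure D3:**
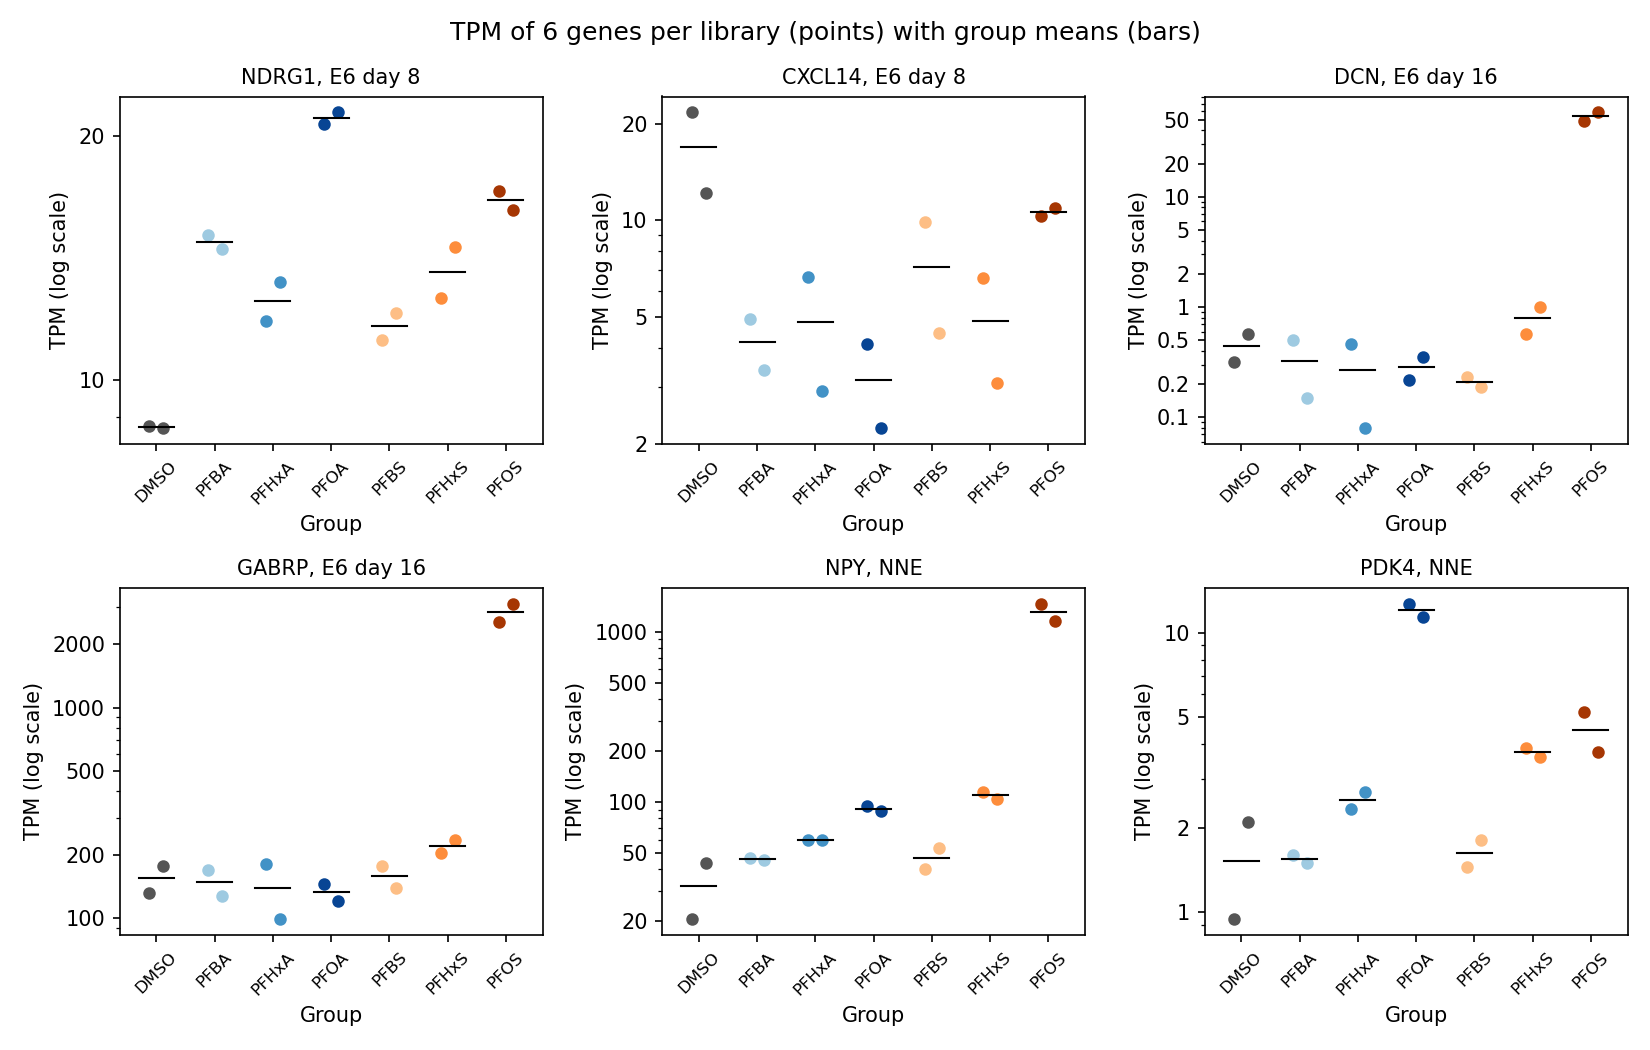
TPM of 6 genes in each library of 1 system (vertical axes, log10 scale), by group (horizontal axes), with 1 point per library and a bar at the mean of the 2. At day 16 DCN and GABRP lie above the DMSO libraries in both PFOS libraries, and in NNE PDK4 lies above them in both PFOA libraries.

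Some lists fixed for other cell types or responses were not called by camera for any compound, which does not show that they were unchanged. With PFOS at day 16, mesodermal genes had 4 higher and 2 lower of 11, and endothelial and blood genes 1 higher of 6. Endodermal genes had 1 higher and 1 lower of 6 and xenobiotic receptor targets 2 higher and 3 lower of 13, each count also over the list alone. Camera gave adjusted p = 0.407, adjusted p = 0.26, adjusted p = 0.729 and adjusted p = 0.932 in this order. The xenobiotic test pointed down while its median was 0.24 (0.37 and 0.059 without PFOS replicate 1 and 2). RUNX1, a factor of blood, rose from 8.54 to 28.1 TPM, and GATA6, a factor of endoderm and heart, from 0.245 to 1.26 TPM. CYP1B1 rose from 6.1 to 12.2 TPM, while CYP1A1, a target of the aryl hydrocarbon receptor, fell from 31.1 to 7.07 TPM. Cholesterol synthesis at day 16 had 10 higher and 3 lower of 23 (11 and 3 adjusted over the list alone) and fatty acid synthesis in NNE 2 higher and 7 lower of 11 (also over the list alone) with PFOS, both without a camera call (adjusted p = 0.145 and adjusted p = 0.0558).

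The compounds differ by chain length and by head group, which a test of the difference itself compares at the same dose. PFOS differed from PFHxS by 1086 genes at day 8, 5650 at day 16 and 3117 in NNE, from PFBS by 1267, 5353 and 3730, and from PFOA, which has the other head group, by 1854, 6299 and 2675. LIFR, a cytokine receptor subunit, stood at 10.8 TPM with PFOS and 3.72 TPM with PFHxS at day 8, a log2 difference of 1.48 ± 0.084 (SE, n = 2 per group; adjusted p = 1.16e-07). The phosphatase INPP5D stood at 5.38 against 86.9 TPM at day 16 (log2 difference -3.87 ± 0.123, adjusted p = 2.17e-10), and the lipid transfer protein PLTP at 18.1 against 56.9 TPM in NNE (log2 difference -1.66 ± 0.078, adjusted p = 5.19e-06). Among carboxylic acids, PFOA exceeded PFHxA in 14 genes at day 8 and was lower in 1, with NDRG1 at 21.1 against 12.5 TPM, and exceeded PFBA in 3, PFKFB4, PPFIA4 and SLC16A3, of which the last was named after its value was seen. In NNE edgeR called 1 gene between PFOA and PFBA, PDK4 (12 against 1.54 TPM), and DESeq2 called 20.

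Any difference among the 6 compounds was called for 1059 genes at day 8, 4922 at day 16 and 2203 in NNE. The count was 346 without PFOS replicate 1 and 394 without PFOS replicate 2 at day 8 (665 without PFOA replicate 2), 2560 without PFOS replicate 2 at day 16, and 585 and 963 without PFOS replicate 1 and 2 in NNE. The 15 genes between PFOA and PFHxA were 0 without PFOA replicate 1, PFOA replicate 2 or PFHxA replicate 1 and 28 without PFHxA replicate 2. The 3 genes between PFOA and PFBA were 1 without PFOA replicate 1 or PFBA replicate 1 and 0 without the other replicate of either. PDK4 was lost without each of the 4 libraries. For the PFOS pairs with PFHxS, PFBS and PFOA, leaving out any of the 4 libraries at day 8 moved the count by more than 1.5 times, to as few as 354, 523 and 542, and so did any except PFOS replicate 2 in NNE, to as few as 1383, 1848 and 1063. At day 16 PFOS minus PFHxS had 3691 and PFOS minus PFBS 3396 genes without PFOS replicate 2.

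The remaining 15 pairs had 0 calls in edgeR, with 166 to 1230 genes at an unadjusted p under 0.05 and 0 to 34 calls in DESeq2. PFHxA minus PFBA at day 8 had 36 calls without PFHxA replicate 2. At day 16 PFBS minus PFBA had 1 without PFBA replicate 1 or PFBS replicate 2, PFHxA minus PFBA 1 without PFBA replicate 1, and PFOA minus PFBA and PFOA minus PFHxA 1 each without PFOA replicate 2. For one gene, the unadjusted 95% interval of such a difference reached a median of 0.17 to either side at day 8, 0.20 at day 16 and 0.23 in NNE on the log2 scale. For the mean of the glycolysis list at day 8, PFOA exceeded PFBA by 0.44 (95% interval 0.21 to 0.68) and PFHxA by 0.51 (0.27 to 0.74), whereas PFHxA and PFBA differed by -0.07 (-0.3 to 0.17) and PFHxS and PFBS by 0.14 (-0.09 to 0.38). For cholesterol synthesis at day 8 the differences were smaller and their intervals narrower. PFOA exceeded PFHxA by 0.18 (0.15 to 0.21) and PFBA by 0.13 (0.1 to 0.16). PFHxA and PFBA differed by -0.05 (-0.08 to -0.03) and PFHxS and PFBS by 0.06 (0.03 to 0.09). At day 16 the interval of this list was wider, with PFOA minus PFHxA at -0.15 (-0.32 to 0.03). The list intervals are not adjusted for the number of lists and pairs, so small differences such as these are not established. For the mean of the 17 PPAR targets in NNE, PFOA exceeded PFBA by 0.47 (0.36 to 0.58) and PFHxA by 0.36 (0.25 to 0.47), PFHxS exceeded PFBS by 0.28 (0.16 to 0.39), PFOS and PFOA differed by -0.2 (-0.32 to -0.09), and PFBS and PFBA differed by -0.07 (-0.18 to 0.05). The 4 genes called with PFOA carried most of its excess, with 1.74 (1.28 to 2.19) over PFBA and 1.42 (0.97 to 1.88) over PFHxA. Over the 13 other members the same differences were 0.08 (-0.09 to 0.24) and 0.03 (-0.13 to 0.2). That of PFHxS and PFBS was 0.14 (-0.03 to 0.3) and that of PFOS and PFOA -0.1 (-0.26 to 0.07). The members were split by their call in the same PFOA libraries. That choice in part fixes the PFOA differences of both parts, and their intervals make no allowance for it. For the p53 targets at day 16, PFOS and PFOA differed by -1.04 (-1.21 to -0.88) and PFHxS and PFHxA by 0.11 (-0.06 to 0.28).

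Whether an effect changed between day 8 and day 16 was tested as an interaction. The PFOA effect on NDRG1 was lower at day 16 than at day 8 by a log2 difference of -1.24 ± 0.137 (SE, n = 2 per group; adjusted p = 0.000115) and that on PFKFB4 by -0.97 ± 0.132 (adjusted p = 0.00171). The PFOS effect on CDH3, a placental and basal cadherin, was higher at day 16 by 1.91 ± 0.103 (adjusted p = 9.03e-11) and that on AFAP1L2 by 2.84 ± 0.164 (adjusted p = 1.5e-10). edgeR called 3934 genes for PFOS (1838 higher, 2096 lower at day 16 than at day 8) and 282 for PFOA (172 higher, 110 lower), and 1 for PFBA. The PFOA count was 10 without day 8 DMSO replicate 1, 6 without day 8 PFOA replicate 2, 127 and 468 without day 16 DMSO replicate 1 and 2, 461 without day 8 DMSO replicate 2, and 71 and 132 without day 16 PFOA replicate 1 and 2. The PFBA count was 0 without day 8 DMSO replicate 1, day 8 PFBA replicate 2, day 16 DMSO replicate 1 or either day 16 PFBA library. It was 31 without day 8 DMSO replicate 2, 3 without day 8 PFBA replicate 1 and 2 without day 16 DMSO replicate 2. PFHxA, PFBS and PFHxS gave 0 calls in edgeR, with 1205, 1466 and 1524 genes at an unadjusted p under 0.05 and 41, 8 and 11 calls in DESeq2. Without day 8 DMSO replicate 2 these counts were 50, 5 and 9. PFHxA had 47 without day 16 DMSO replicate 1, and PFHxS had 5 without day 16 DMSO replicate 2 and 2 without day 8 PFHxS replicate 1.

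Many genes that PFOS changed were called in more than 1 system. At day 16 and in NNE, 982 genes were higher and 840 lower in both, against 517 and 500.1 for independent lists (two-sided Fisher's exact test, p = 6.13e-124 and p = 3.34e-70), while 418 and 322 went in opposite directions, against 564.6 and 457.9. Day 8 and day 16 shared 190 higher and 129 lower genes, against 105.6 and 60.3 (Fisher's exact test, p = 6.79e-18 and p = 4.44e-19). A further 142 genes higher and 68 lower at day 8 went the opposite way at day 16, against 101.9 and 62.5. Day 8 and NNE shared 135 higher and 95 lower genes, against 92.5 and 61.6 (Fisher's exact test, p = 2.04e-06 and p = 5.28e-06), while 158 and 66 went in opposite directions, against 101.8 and 56. For PFOA, day 8 and NNE shared 4 higher genes, against 4.3 (Fisher's exact test, p = 1), and 10 lower ones, against 5.3 (p = 0.0421). Another 9 and 6 went in opposite directions, against 5.3 and 4.4. DESeq2 calls for PFOA shared 22 higher genes, against 14.9 (Fisher's exact test, p = 0.0597), and 51 lower ones, against 16.3 (p = 2.57e-13). In opposite directions went 29 and 29, against 17.7 and 13.7, so these exceeded independent lists too. Only shared directions were tested, and genes are not independent replicates. The genes called in the same direction in the largest number of the 18 comparisons were ALDH1A3, which makes retinoic acid, PTCHD4, BMP2 and SPATA18, lower in 7 each, and the cold-inducible gene CIRBP, higher in 7. These 7 comparisons include PFBA, PFHxA and PFHxS at day 8, in which all 5 genes lost their call without DMSO replicate 1 (adjusted p from 0.0711 to 0.365), and also without PFBA replicate 2, PFHxA replicate 1 or PFHxS replicate 2 of the compound concerned (adjusted p from 0.0544 to 0.344). ALDH1A3, PTCHD4 and SPATA18 lost it without PFHxA replicate 2 as well, and SPATA18 without PFHxS replicate 1 (adjusted p from 0.104 to 0.202). With PFOS at day 8, ALDH1A3 and CIRBP lost it without DMSO replicate 1 or either PFOS library and BMP2 without any of the 4 libraries (adjusted p from 0.066 to 0.317). PTCHD4 lost its NNE call with PFOS without any of the 4 libraries, and BMP2 without DMSO replicate 1 or PFOS replicate 1 in NNE and PFOS replicate 1 at day 16 (adjusted p from 0.0528 to 0.203).

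Within a system the compounds share their DMSO libraries, so their fold changes correlate even without an effect: unchanged simulated groups gave a correlation of 0.5. Across genes, which are not independent replicates, pairs of compounds other than PFOS correlated at 0.70 to 0.85 at day 8, and pairs with PFOS at 0.24 to 0.34. At day 16 all pairs lay between -0.02 and 0.62 and in NNE between 0.60 and 0.86. The covariance of PFBA and PFOA at day 8 was 0.0466 against 0.00834 in the simulation. That of PFOA and PFOS in NNE was 0.127 against 0.0166. These 2 pairs had the largest excess of their systems. Pairs with PFOS at day 8 had covariances of 0.00935 to 0.0201, each above the simulated value despite their low correlations. At day 16 covariances ranged from -0.00167 for PFOA and PFOS to 0.024 for PFHxS and PFOS, most of them below the simulated 0.0104. PFBA and PFOA shared 363 higher and 384 lower calls at day 8, against 27.8 and 28.9 for independent lists. Unchanged simulated groups had at most 2 calls per compound and at most 1 shared call, too few to serve as a reference for lists of this size. PFOA and PFOS shared 180 higher and 180 lower calls at day 8, against 39 and 21.6. The 2 DMSO libraries of a system cannot be split into parts of 2, so part of this excess may come from the shared controls.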

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

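The tests of single genes and of counts between days were planned, while the tests of gene lists between days and the comparison of PFOA with other compounds without DMSO were chosen after the results were seen. Each value here is a difference of a compound's effect between day 16 and day 8 that passed the interaction test in edgeR or, for a list, camera on it, which is what singled it out, except where a missed call is stated. For PFOS 3934 genes differed, with CDH3 higher by 1.91 and AFAP1L2 by 2.84 on the log2 scale. The neuroectoderm list was lower at day 16 in 13 of 16 members, with a median difference of -2.27 (camera adjusted p = 5.82e-16; adjusted p = 0.0875 with an estimated correlation). Matrix genes were higher in 14 of 18 (median 0.94; adjusted p = 3.34e-12; adjusted p = 0.0875 with an estimated correlation). For PFBA 1 gene differed, and 0 did in edgeR without day 16 DMSO replicate 1, day 8 DMSO replicate 1, day 8 PFBA replicate 2 or either day 16 PFBA library (973 to 1621 genes at an unadjusted p under 0.05); DESeq2 called 33 with all libraries.

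For PFOA 282 genes differed, and the effect was lower at day 16 by -1.24 for NDRG1 and -0.97 for PFKFB4. The count was 10 without day 8 DMSO replicate 1, 6 without day 8 PFOA replicate 2, 127 and 468 without day 16 DMSO replicate 1 and 2, 461 without day 8 DMSO replicate 2, and 71 and 132 without day 16 PFOA replicate 1 and 2. Of 18 glycolysis and hypoxia genes 10 were lower at day 16 (median -0.62; camera adjusted p = 3.72e-23; adjusted p = 0.0875 with an estimated correlation). The median of this list was lower at day 16 with the other compounds too: -0.86 with PFOS (12 lower and 2 higher; adjusted p = 5.99e-12), -0.43 with PFHxS (3.72e-13), -0.26 with PFBA (3.35e-07), -0.23 with PFBS (8.98e-07) and -0.20 with PFHxA (7.4e-05). With an estimated correlation the adjusted p was 0.178, 0.152, 0.254, 0.258 and 0.338. Of 18 non-neural ectoderm genes 6 were higher with PFOA (median 0.49; adjusted p = 1.42e-11; adjusted p = 0.205 with an estimated correlation). The median was also higher with PFBA (0.55; adjusted p = 5.86e-09), PFHxA (0.50; 5.82e-10), PFBS (0.34; 7.89e-07) and PFHxS (0.29; 7.97e-06), and with an estimated correlation the adjusted p was 0.254, 0.25, 0.28 and 0.338. With PFOS it was 0.26 without a camera call (5 higher and 4 lower; adjusted p = 0.106). All 6 compounds were compared with the same DMSO libraries of each day.

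The higher glycolysis and hypoxia genes with PFOA at day 8 were weighed against an effect of the DMSO libraries alone. With no DMSO library in the comparison, the list mean of PFOA lay 0.491 above that of PFBA, PFHxA, PFBS and PFHxS. The exact two-sided permutation test gave p = 0.0222, the smallest that the 45 splits of 10 libraries can give. PFOA and the list were chosen for this test after the results were seen, for which the p-value makes no allowance. The test also treats the 10 libraries as exchangeable, whereas the libraries of a group may be technical, so the p-value may be too small. The DMSO libraries have no part in this difference, but chance in the PFOA libraries stays open. PFOS, which was not in that comparison, lay below PFOA too (list mean difference -0.33, 95% interval -0.57 to -0.1). A response of the cells to PFOA was not tested apart from these values and stays open, as do oxygen, cell density and glucose in these cultures, which were not analysed here.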

How the results depend on the processing

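The alternatives named here were planned, except the test of the DMSO replicates at day 8, which was chosen after the result was seen. Of 77 gene counts, shared calls included, DESeq2 left 42 within 1.5 times, raised 31 and lowered 4; RLE normalisation left all 39 of its counts within 1.5 times, and no filter on low counts 17 of 21. RLE moved the median of all genes by at most 0.004 and the share of higher against lower calls by at most 8.3 points. Leaving out 1 library left 204 of 314 counts within 1.5 times, raised 34 and lowered 76. In all of these tallies a count of 0 that stayed 0 was taken as within 1.5 times. The tallies therefore do not show how stable the counts above 0 were. Of 161 calls of named genes in a comparison, 124 held in every alternative run, none changed direction, and leaving out 1 library ended a call in 105 of 690 gene fits. These 161 were all calls of the main fit, and many were picked for a large change or a small p. That choice makes a change of direction unlikely from the start, so these figures do not describe other genes. The planned pseudocount alternative was for a file without counts and was not run. The cause of the changes below was not tested.

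With DESeq2, day 8 gave 63 genes for PFBS (against 0 in edgeR), 599 for PFOS (905), 29 for PFOA minus PFHxA (15), 11 for PFOA minus PFBA (3), 15 for PFHxA minus PFBA (0), 690 for PFOS minus PFHxS (1086), 782 for PFOS minus PFBS (1267), 1205 for PFOS minus PFOA (1854), and 1 each for PFHxS minus PFBS and PFHxS minus PFHxA (0). Day 16 gave 3 for PFBA, 2 for PFHxA, 16 for PFOA, 4 for PFHxS, 34 for PFOA minus PFHxA, 15 for PFOA minus PFBA and 1 each for PFHxS minus PFBS and PFBS minus PFBA (0 in edgeR for each), and 41 for the mean of the 6 compounds (3). NNE gave 5 for PFHxA, 48 for PFBS, 275 for PFHxS, 8 for PFOA minus PFHxA, 7 for PFHxS minus PFBS and 2 for PFBS minus PFBA (0 for each), 654 for PFOA (154) and 20 for PFOA minus PFBA (1). Between days it gave 33 for PFBA (1), and 41, 8 and 11 for PFHxA, PFBS and PFHxS (0). DESeq2 calls shared by systems were 1 for PFOA at day 8 and day 16, 73 for PFOA at day 8 and in NNE, 2 for PFOA at day 16 and in NNE, and 6 for PFHxS at day 8 and in NNE.

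With no filter on low counts the calls were 25 for PFBS at day 8, 1 for PFBA and 12 for the mean at day 16, and 234 for PFOA in NNE. Fits of only the 4 libraries compared, with fewer libraries to estimate the spread, gave 1 for PFBS and 110 for PFHxS at day 8, 3 for PFBA, 1 for PFHxA, 1 for PFBS and 3 for PFHxS at day 16, and 0 for PFOA in NNE. With a correlation estimated from the data, 1 list was called for PFOA at day 8 (12 at a correlation of 0.01), and 0 for each other compound and system (3 to 13).

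The libraries share only a replicate number. Deviations of same-numbered libraries from their group means correlated at a median of 0.08 at day 8, 0.03 at day 16 and 0.25 in NNE. They were over 0.1 in 8, 3 and 18 of 21 pairs of groups (in NNE in all 15 pairs of compounds, at 0.17 to 0.48). A library's best partner had its own number for 14, 12 and 14 of 14 libraries, a hint from the data and not the design. The 2 deviations of a group mirror each other, so its 2 libraries count as 1 observation here. With a replicate block, day 8 gave 1862 genes for PFBA, 1215 for PFHxA, 398 for PFBS, 1337 for PFHxS, 1579 for PFOS, 2329 for the mean, 2227 for any difference, 130 for PFOA minus PFHxA, 30 for PFOA minus PFBA, 2020 for PFOS minus PFHxS, 2078 for PFOS minus PFBS and 2869 for PFOS minus PFOA. Under the block day 16 gave 7 for the mean, 2 for PFOA minus PFHxA and 1 for PFOA minus PFBA. NNE gave 1892 for PFOA, 646 for PFHxS, 3223 for the mean, 4227 for any difference, 7 for PFOA minus PFHxA, 37 for PFOA minus PFBA, 4805 for PFOS minus PFHxS and 4284 for PFOS minus PFOA. Between days the block gave 117 for PFBA, 97 for PFHxA, 718 for PFOA, 9 for PFBS and 35 for PFHxS. The other 49 counts stayed within 1.5 times.

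Without 1 library each, day 8 gave 5 to 920 genes for PFBA, 0 to 684 for PFHxA, 499 to 1856 for PFOA, 0 to 114 for PFBS, 0 to 514 for PFHxS, 325 to 612 for PFOS, 16 to 1471 for the mean and 346 to 1081 for any difference. Its pairs gave 0 to 28 for PFOA minus PFHxA, 0 to 1 for PFOA minus PFBA, 0 to 36 for PFHxA minus PFBA, 354 to 635 for PFOS minus PFHxS, 523 to 795 for PFOS minus PFBS and 542 to 998 for PFOS minus PFOA. Day 16 gave 0 to 12 for PFHxA, 0 to 3 for PFOA, 3777 to 5123 for PFOS, 0 to 35 for the mean and 2560 to 5092 for any difference, 3691 to 4847 for PFOS minus PFHxS, 3396 to 4522 for PFOS minus PFBS, and 0 to 1 for PFBS minus PFBA, PFHxA minus PFBA, PFOA minus PFBA and PFOA minus PFHxA. NNE gave 0 to 104 for PFBA, 0 to 242 for PFHxA, 0 to 696 for PFOA, 0 to 114 for PFBS, 0 to 518 for PFHxS, 3465 to 4767 for PFOS, 0 to 1409 for the mean, 585 to 1919 for any difference, 1383 to 2158 for PFOS minus PFHxS, 1848 to 2633 for PFOS minus PFBS, 1063 to 1883 for PFOS minus PFOA and 0 in each fit for PFOA minus PFBA. Between days the ranges were 0 to 31 for PFBA, 0 to 50 for PFHxA, 6 to 468 for PFOA, 0 to 5 for PFBS and 0 to 9 for PFHxS.

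For PFBA, PFHxA and PFHxS at day 8, the median change of called genes against DMSO replicate 2 alone was 0.746 to 0.801 of that against DMSO replicate 1 alone. These genes were called with both DMSO libraries in the test, which favours genes that differ from both. The ratio therefore cannot tell how far DMSO replicate 1 set these calls. With 2 libraries per group and simulated recovery of 71.6% (day 8), 74.6% (day 16) and 49.3% (NNE) of 1.5-fold changes for PFOA, smaller changes were often not detectable.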

Other observations

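The tests on hallmark sets and all tests of explanations below were chosen after the results were seen. The hallmark sets of the deposited table describe further gene groups. With PFOS in NNE, 77 of 168 genes of TNF signalling by NF-kappaB fell and 17 rose (median -0.43; camera adjusted p = 1.84e-06; adjusted p = 0.381 with an estimated correlation). Of 176 genes of epithelial-mesenchymal transition 76 fell and 27 rose (median -0.39; adjusted p = 4.65e-06; adjusted p = 0.124 with an estimated correlation). Of 47 genes of the reactive oxygen species pathway 27 fell and 7 rose (adjusted p = 0.000138; adjusted p = 0.309 with an estimated correlation). At day 16 PFOS moved the transition set the other way, with 77 of 189 higher and 45 lower (adjusted p = 0.00155; adjusted p = 0.997 with an estimated correlation). Of 197 E2F target genes 76 fell and 11 rose at day 16, with the same pair of adjusted p-values. The difference between the systems was not tested. At day 8, 9 of 33 genes of hedgehog signalling rose with PFOS and 0 fell (adjusted p = 0.000247; adjusted p = 0.183 with an estimated correlation). Of 192 genes of the G2/M checkpoint 52 rose with PFOA and 8 fell (adjusted p = 3.25e-05; adjusted p = 0.936 with an estimated correlation).

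In the authors' deposited table, 853 genes had a q-value under 0.05 for PFOA at day 8, 3262 for PFOS at day 16 and 3367 for PFOS in NNE, and 831, 3249 and 3192 of these were called here too. For PFOA in NNE the table had 376 such genes, of which 95 were among the 154 called here, and for PFHxS in NNE and PFBS at day 8 it had 121 and 12, where edgeR called 0 (2176 and 1951 genes at an unadjusted p under 0.05) and DESeq2 275 and 63.

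The fall of p53 target genes with PFOS at day 16 and in NNE kept at least 0.964 of its median after correction for gene length and expression level, which argues against such a bias. At day 16, where the median was -0.703 beside -2.22 for neuroectoderm genes, loss of neural ectoderm cells that carry these transcripts and a fall within cells cannot be told apart, since both lower every member. In NNE, where the p53 target median was -0.991 without DMSO replicate 1, the DMSO cells argue against that loss: of 11 neuroectoderm genes with at least 20 TPM at day 8, 10 stood in NNE at under 0.02 of the day 8 level (median ratio 0.00162; NES, at 0.727, was the exception), far below the 0.497 of cells that would have to be lost if all cells carried these transcripts alike. Lower transcription of p53 target genes is a candidate explanation. Loss of other cell types that carry these transcripts was not tested and stays open in both systems. Either would lower p53 pathway genes outside the list, so their values cannot tell the 2 apart. Those genes had medians of -0.11 (183 genes, 67 lower and 39 higher) and -0.18 (176 genes, 67 lower and 24 higher), at percentile 0 of 10000 expression-matched lists in both systems. Camera called this hallmark set in NNE (adjusted p = 0.000186; adjusted p = 0.381 with an estimated correlation) and not at day 16 (adjusted p = 0.174).

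The PPAR target genes called with PFOA in NNE, PDK4, ANGPTL4, CPT1A and ACADVL, numbered 1, 4, 0 and 1 without DMSO replicate 1, DMSO replicate 2, PFOA replicate 1 and PFOA replicate 2, so the 2 DMSO libraries were left out in a further test. The whole list of 17 lay 0.405 above PFBA, PFHxA, PFBS and PFHxS (exact two-sided permutation p = 0.0222, the smallest possible). DMSO replicate 1 of NNE has no part in this difference. The p-value makes no allowance for the choice of PFOA and of this list after the results were seen. The test also treats the libraries as exchangeable. Deviations of same-numbered libraries of these compounds correlated at 0.31 to 0.48 in NNE, and the 2 libraries of a group may be technical. Its p-values may therefore be too small. The 4 called genes carried the difference of 0.405: their mean lay 1.54 above the same compounds, and that of the 13 other members 0.0547 above (exact two-sided permutation p = 0.489). Members were split by their call in the same PFOA libraries, which in part fixes both values. A shift of the list as a class was not shown, and this split cannot decide it. A response of these 4 genes to PFOA stays open, as does chance in the PFOA libraries, with which they were selected. No test of the difference between NNE and E6 was run.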
